A study of Homo sapiens with 4 samples.

How the data were processed

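RNA sequencing of 4 libraries was used, 1 for each of 4 groups, namely HCC1937 and THP-1 cells labelled as carrying p53-R282W, each untreated and with DAC. Per the labels, total RNA was extracted and libraries were made from purified mRNA with an Illumina TruSeq kit. Per the submitters' processing notes, FastQC, cutadapt, STAR and HTSeq were run against hg38. Versions, the gene annotation and strand use in counting are not given there. The deposited table gives no unit. Its values were taken as FPKM computed by the authors, for 3 reasons found in the values. They have 2 decimals, their column sums differ, and for short genes (exon length 50 to 250 bp in GENCODE 29) value times length falls on whole multiples of a single step, within 0.1, in 94.5% to 95.4% of genes. That step gives counted reads of 18.7 M in both HCC1937 libraries and of 19.5 M and 19.6 M in the untreated and DAC libraries of THP-1. The THP-1 columns hold no value in 37039 of 60612 table lines and imply other gene lengths. They appear to come from another gene set joined by symbol, so differences are taken within a line and levels are compared between lines only roughly.

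The table lines of 76 symbols that occur more than once (1079 lines) were left out, and 59533 genes were analysed, 23440 of them with THP-1 values. The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. That plan assumed counts. Since the values are FPKM, the size rule it held ready for normalised values replaced the planned count rule, and limma replaced the planned count test. A gene was kept in a line at 1 FPKM or more in at least 1 library of the pair, and called at a difference of at least 2-fold on log2(FPKM + 1). Deposited values were not rescaled in the main results. Reads per gene were estimated from FPKM, the step and approximate exon lengths. They give exact (Clopper-Pearson) 95% intervals of a ratio, which cover counting error only and not the differences between cultures.

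For each of 32 gene lists written from general knowledge, the median log2 difference of kept members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of these, and at least 3 kept members were required. No p-value is attached. By chance 5% of lists would lie outside if their members varied independently, since random members were drawn singly. Members of a list may vary together between any 2 cultures, which would put more lists outside without an effect of DAC. Shared calls were set against the overlap of independent lists over the genes kept in both lines. Over both lines, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with line as a block and an intensity trend, with Benjamini-Hochberg adjustment at 0.05 over all genes and, separately, adjusted over the list alone. Its residual is the difference between the lines in their response, on 1 degree of freedom. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

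The naming rule took, per line and direction, the 12 called genes with the largest difference among those with at least 5 FPKM in the higher library. It took up to 8 per direction called in both lines, up to 5 limma calls per direction, up to 4 members of each list with the largest difference per line, and set genes, among them CDKN1A, MDM2, DNMT1, DNMT3A and DNMT3B. Clone-based and unnamed loci were counted and not named. Alternatives were median-of-ratios and upper-quartile scaling within each pair, other filters, pseudocounts and sizes of change, and limma without the block or at another threshold. Alternatives chosen after seeing the data were the counting interval as a rule, leaving out short genes (exons under 300 bp or small RNA types), and limma without the intensity trend or with upper-quartile scaling.

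The procedure was tested on simulated data in 10 draws, with 200 genes changed in each and a dispersion of 0.01 about the observed read numbers. The changed genes were drawn from those with at least 2 FPKM untreated in both lines. The size rule recovered on average 26.8% of 2-fold and 92.0% of 3-fold changes in HCC1937, and 36.0% and 95.4% in THP-1. It called 15 to 33 of about 10186 unchanged genes in HCC1937 and 66 to 93 of about 11408 in THP-1. A gene without untreated reads stayed without reads in these draws and could not be called. Only genes with values and lengths in both lines were simulated, and the dispersion was not estimated from replicates. These numbers therefore do not give the false calls among the genes reported below, nor the share recovered among genes that are low untreated. Of the higher genes, 68.3% in HCC1937 and 71.7% in THP-1 were below 1 FPKM untreated. With changes equal in both lines, limma recovered 94.0% of 2-fold changes (78 to 100% by draw), with 7 to 89 of about 12324 unchanged genes called.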

Results

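Gene expression was measured by RNA sequencing in 4 libraries of 2 human cancer cell lines. HCC1937 is a breast cancer line and THP-1 a monocytic leukaemia line. The labels describe both as lacking p53 and as infected with p53-R282W, a mutant form of the tumour suppressor. In each line 1 library came from untreated cells and 1 from cells given decitabine (DAC), a deoxycytidine analogue that inhibits DNA methyltransferases. HCC1937 received 0.3 µM for 5 days and THP-1 received 5 µM for 2 days. The question set by the labels is how DAC alters expression in cells carrying this mutant. With 1 library per group there is no spread between replicates, so no p-value is given within a line. Such differences describe these libraries, and any interval beside them covers counting error only. Values are FPKM (fragments scaled to exon length and to the reads counted in a library), and positions are on hg38 from the GENCODE 29 annotation. The spacing of the values puts the depth at 18.7 M counted reads in both HCC1937 libraries, and at 19.5 M and 19.6 M in the untreated and DAC libraries of THP-1. At that depth 1 FPKM of a 2 kb gene is 37.4 to 39.2 reads.

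The libraries carried the marker genes of the lines they are labelled as. Of 35 epithelial and basal breast markers, 33 reached 1 FPKM in untreated HCC1937 and 6 did in untreated THP-1. Of 21 myeloid progenitor genes, 2 reached it in untreated HCC1937 and 18 in untreated THP-1. No library without the transgene was included, and the THP-1 values rest on other gene lengths, so differences are taken within a line and levels are compared between lines only roughly.

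In HCC1937, genes of germ cells and testis that were at or near 0 untreated stood among the highest gains with DAC. VCX2 (ENSG00000177504.10, X, 8169944 to 8171267), a testis gene of the X chromosome, was listed at 0 untreated and stood at 168 FPKM with DAC. DAZL (ENSG00000092345.13, chromosome 3, 16586792 to 16670306), a germ cell RNA-binding protein, went from 0.06 to 65.7 FPKM. GSTP1 (ENSG00000084207.16, chromosome 11, 67583595 to 67586656), a glutathione transferase, went from 0.09 to 84.9 FPKM, which is 944-fold with a 95% counting interval of 346 to 4909. KRT19 (ENSG00000171345.13, chromosome 17, 41523617 to 41528308), a keratin of simple epithelia, went from 3.87 to 294 FPKM, 76.0-fold with an interval of 65.3 to 89.0. The largest drops included FAM20C, a secretory pathway kinase (65.1 to 9.15 FPKM), KRT15, a basal keratin (95.5 to 16.5 FPKM), and DDIT4, a stress-induced inhibitor of mTOR signalling (297 to 59.6 FPKM).

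Of 14058 genes kept in HCC1937, 1452 were at least 2-fold higher in the DAC library and 202 at least 2-fold lower. The higher genes included 904 protein-coding genes, and 992 of the 1452 (68.3%) were below 1 FPKM untreated, 380 of them listed at 0. The lower genes included 87 protein-coding genes and 51 small RNAs. Higher genes made up 87.8% of the called genes, against 80.7% under median-of-ratios scaling (1238 higher, 296 lower) and 68.6% under upper-quartile scaling (1063 higher, 487 lower). The median log2 difference of all kept genes was 0.19 as deposited. It was 0.06 and -0.08 under these scalings, and the differences below are to be read against that shift. Among the other genes with the largest gains, PRR20G went from 0.1 to 78.1 FPKM, NNAT, an imprinted neuronal gene, from 0.36 to 53 FPKM, and GCNA, a germ cell protein, from 0.09 to 41.1 FPKM. VCX3A (59.8 FPKM), CT45A1 (49.7 FPKM), TKTL1 (37.3 FPKM), TUBA3E (33.7 FPKM) and MAGEA4 (33.0 FPKM) were listed at 0 untreated. The VCX, CT45A, PRR20 and TUBA3 genes have close copies in the genome, so the split of reads among copies is uncertain. Among the lower genes, MT2A, a metal-binding metallothionein, stood at 1343 FPKM untreated and 307 with DAC, and TNFAIP2, a gene induced by tumour necrosis factor, at 493 and 157. SNHG19 (43.8 and 8.74 FPKM), C15orf48 (73.7 and 18.4 FPKM), TSC22D3, a glucocorticoid-induced gene (81.4 and 23.8 FPKM), and IL1B, an inflammatory cytokine (26.9 and 7.84 FPKM), were lower as well. UNC5A, a netrin receptor, was lower by the same rule, with a log2 difference of -1.73. MIR205 and MIR200A also passed, on few reads.

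The cancer-testis list, antigens silenced by promoter methylation in most somatic cells, had 25 of 26 kept members at least 2-fold higher in the HCC1937 DAC library and 0 lower. Its median log2 difference was 2.12, and random lists matched on expression ran from 0.18 to 0.76 (their central 95%). Of these 26, 25 passed the filter through the DAC library alone, which favours gains. Over the 41 members above 0 in at least 1 library the median was 1.18, still above its random lists. Members at 0 in both libraries are left out there, so that set favours gains as well. Germline and meiosis genes had 15 of 20 higher and 0 lower (median 1.55, random 0.14 to 0.81), such as TUBA3D and DPEP3, both listed at 0 untreated and at 30.7 and 9.28 FPKM with DAC. Of these 20, 16 were kept through the DAC library alone. Over the 37 germline genes above 0 in at least 1 library the median was 0.77, still above its random lists, with the same limit. Interferon-stimulated genes had 10 of 40 higher and 0 lower (median 0.62, random -0.05 to 0.26). IRF7, a transcription factor of the interferon response, stood at 0.12 FPKM untreated and 17.3 with DAC, IFI6 at 71.1 and 345, IFI27 at 27.3 and 147, and OAS3, a sensor of double-stranded RNA, at 11.9 and 40.2. Mesenchymal genes had 6 of 14 higher and 0 lower (median 0.71, random -0.03 to 0.54), among them THY1 at 0.02 FPKM untreated and 2.34 with DAC. That list was no longer apart without the filter, at a median of 0.19, or with a pseudocount of 10. Epithelial genes had 6 of 34 higher and 1 lower, against 6 and 2 under median-of-ratios scaling and 5 and 4 under upper-quartile scaling. Their median of 0.11 lay just above the random range of -0.23 to 0.10 and turned negative under both scalings, and the list was no longer apart with genes of at least 5 FPKM or without short genes. Under median-of-ratios and upper-quartile scaling the higher counts were 9 and 6 for interferon-stimulated genes and 5 and 2 for mesenchymal genes. KRT14 (14.9 and 111.8 FPKM) and TP63 (1.56 and 12.2 FPKM), both of basal epithelium, were higher while KRT15 was lower.

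**Figure D1:**
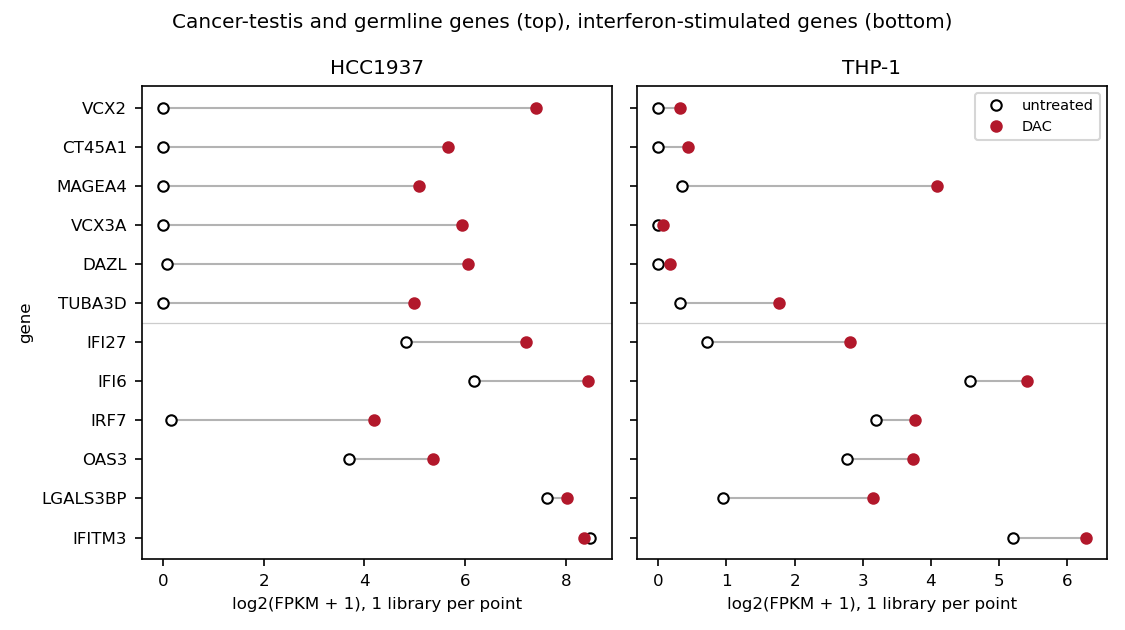
Levels of 6 cancer-testis and germline genes (top) and 6 interferon-stimulated genes (bottom) as log2(FPKM + 1) in the untreated (open) and DAC (filled) library of each line, 1 library per point. MAGEA4 and IFI27 were higher with DAC in both lines, and VCX2, listed at 0 in both untreated libraries, stood at 168 FPKM in the HCC1937 DAC library; the horizontal scales differ between the panels.

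Genes of DNA replication shifted together in HCC1937 without large single differences. Their median log2 difference was 0.40 over 36 kept members (random -0.11 to 0.20), with 0 past 2-fold in either direction. CDC6, a licensing factor, stood at 17.7 FPKM untreated and 35.1 with DAC, and UHRF1, which recruits DNMT1 to replicated DNA, at 17.0 and 31.6. Fanconi anaemia and homologous recombination genes had 2 of 26 higher and 0 lower (median 0.43, random 0.02 to 0.41), the higher being RAD51AP1 (8.05 and 19.6 FPKM) and XRCC2 (1.79 and 4.83 FPKM). Under median-of-ratios and upper-quartile scaling 1 and 0 of that list stayed higher, XRCC2 being lost under both. The replication histones below had 7 and 6 of 14 higher under these scalings, with 1 lower under each. With genes of at least 5 FPKM alone, the Fanconi anaemia and homologous recombination list fell back inside its random range. Replication-dependent histones had 8 of 16 higher and 0 lower (median 0.98, random -0.09 to 0.45), such as H1-2 (18.5 and 96.0 FPKM) and H4C8 (1.38 and 13.3 FPKM). Most of their transcripts lack the poly(A) tail on which mRNA is usually purified. Mitochondrially encoded mRNAs had 2 of 13 higher and 0 lower (median 0.74, random -0.45 to 0.08), and their summed level was 5341 FPKM untreated and 9534 with DAC. MT-ND1, a subunit of respiratory complex I, stood at 125.9 and 255 FPKM. Under both scalings 0 of these 13 were past 2-fold, while the list stayed above its random lists, which move with the scaling too. G2/M genes were not apart from random lists, at a median of 0.18 against -0.14 to 0.18, and that median turned negative under upper-quartile scaling.

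Stress response, sterol and translation genes lay on the lower side in HCC1937. Genes of the unfolded protein and integrated stress response had 0 of 18 higher and 5 lower (median -0.65, random -0.28 to 0.17). HSPA5, the main chaperone of the endoplasmic reticulum, stood at 943 FPKM untreated and 388 with DAC, and HERPUD1 at 67.6 and 29.9. Sterol synthesis genes had 0 of 20 higher and 2 lower (median -0.49, random -0.22 to 0.20). The lower ones were MSMO1 (95.3 and 36.9 FPKM) and HMGCS1 (69.7 and 30.3 FPKM). Ribosomal proteins had 0 of 40 past 2-fold in either direction at a median of -0.46 (random -0.32 to -0.01). Metallothioneins had 2 of 6 higher and 2 lower (median -0.59, random -0.27 to 0.80). MT1X stood at 22.7 and 8.26 FPKM, and MT1A, listed at 0 untreated, at 2.02 with DAC. Without a filter on low values the metallothionein median was 0.08 and no longer apart. In the protocadherin beta cluster 0 of 3 were higher and 2 were lower (median -1.10, random -0.32 to 1.36), PCDHB8 (3.54 and 1.01 FPKM) and PCDHB14 (2.06 and 0.43 FPKM). Of these 3, 2 were kept through the untreated library alone, and without the filter the median was -0.04 over 15 genes, still below its random lists. NF-kB and inflammatory genes went both ways, with 4 of 23 higher and 5 lower (median -0.16, random -0.14 to 0.28). IL6 (2.12 and 15.9 FPKM) and CCL5 (19.6 and 70.1 FPKM), both secreted signals of inflammation, were higher. This list was no longer apart without a filter on low values, with genes of at least 5 FPKM or without short genes. Under median-of-ratios and upper-quartile scaling the lower counts were 6 and 9 for stress response genes, 5 and 8 for sterol synthesis genes and 0 and 5 for ribosomal proteins.

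Direct p53 targets had 7 of 51 higher and 1 lower in HCC1937 (median 0.31, random 0.01 to 0.29). TNFRSF10D, a decoy death receptor, stood at 0.24 FPKM untreated and 14.4 with DAC, and TP53I3, an oxidoreductase, at 4.23 and 12.03. CDKN1A, the cell cycle inhibitor p21, stood at 53.03 and 111 FPKM (log2 1.05), and MDM2, which degrades p53, at 1.77 and 3.45. CDKN1A dropped below 2-fold under both scalings, at log2 0.90 and 0.74, with 4 of 51 higher under each, and the list's median fell back inside its random range under both, under both filters and under both other pseudocounts. Of the DNA methyltransferases, DNMT3B stood at 5.23 and 14.4 FPKM (log2 1.30), DNMT1 at 23.7 and 33.1, and DNMT3A at 1.64 and 2.47.

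A few markers of blood cells, 9 over the myeloid progenitor, monocyte and lymphoid lists, were higher in the HCC1937 DAC library at low levels. Most listed markers were not kept, with 3 of 21 myeloid progenitor, 11 of 36 monocyte and 3 of 23 lymphoid genes passing the filter. Myeloid progenitor genes had 2 of 3 higher and 0 lower (median 1.56, random -0.32 to 1.04), HOXA9 (0.33 and 4.91 FPKM) and CEBPA (2.43 and 9.09 FPKM). Monocyte and macrophage genes had 4 of 11 higher and 0 lower (median 0.69, random -0.08 to 0.68), such as TYROBP, a signalling adaptor, listed at 0 untreated and at 3.24 FPKM with DAC. Of the lymphoid genes, LCK stood at 0.06 and 3.10 FPKM and CD79B at 0.05 and 2.36. All 3 kept lymphoid genes passed the filter through the DAC library alone, so their gains follow from the filter. Over the 17 lymphoid genes above 0 in at least 1 library the median was 0.34, above its random lists. Genes at 0 untreated enter that set only through a gain, so it favours gains as well. Under upper-quartile scaling 2 of 11 monocyte genes were higher and 1 lower. The monocyte list was no longer apart under either scaling, without a filter, without short genes or with a pseudocount of 10, and with genes of at least 5 FPKM it lay at the low end of its random lists. The myeloid progenitor list was no longer apart without a filter on low values, at a median of 0.12 over 16 genes.

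**Figure D2:**
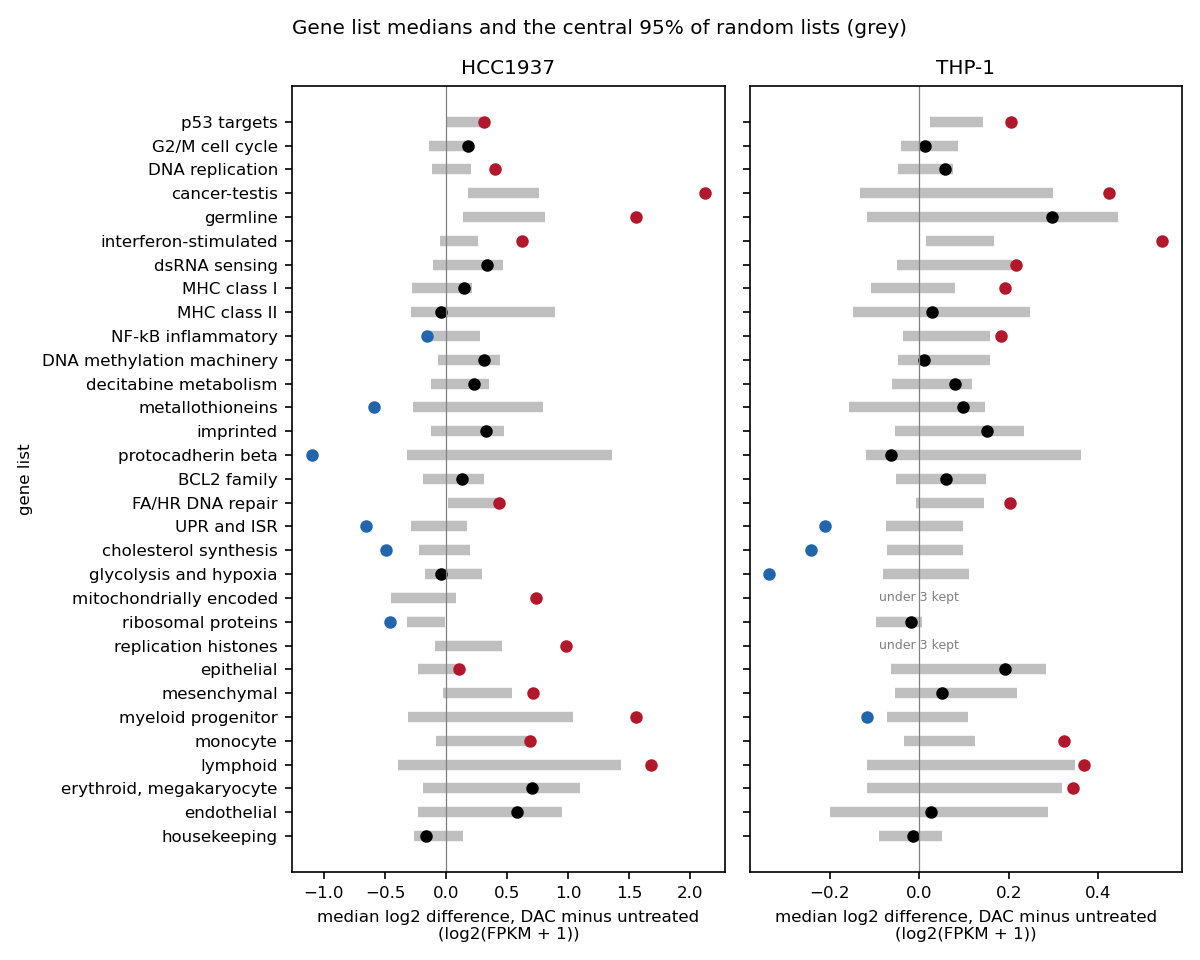
Median log2 difference (DAC minus untreated, on log2(FPKM + 1)) of each gene list in both lines, with grey bars for the central 95% of 10000 expression-matched random lists. Red and blue points lie above and below the bar, 13 and 6 lists in HCC1937 and 10 and 4 in THP-1, and the horizontal scales differ between the panels. At least 1 of both scalings turns the HCC1937 medians of the G2/M, MHC class I, BCL2 family, decitabine metabolism and epithelial lists negative, and in THP-1 those of the G2/M, DNA replication, BCL2 family, DNA methylation machinery, endothelial, mesenchymal and MHC class II lists.

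In THP-1, fewer genes differed, and MAGEA4, PNMA5 and the interferon-stimulated LGALS3BP and IFI27 were among the highest gains. MAGEA4 (ENSG00000147381.11, X, 151912509 to 151925170), a cancer-testis antigen, stood at 0.27 FPKM untreated and 16.1 with DAC, which is 59.5-fold with a counting interval of 32.6 to 127. PNMA5, a gene of the X chromosome, stood at 0.22 and 7.82 FPKM, and UNC13D, which acts in the release of cytotoxic granules, at 3.09 and 12.4. LGALS3BP, a secreted glycoprotein, stood at 0.93 and 7.86 FPKM and IFI27 at 0.64 and 6.01. Of 12075 genes kept, 138 were at least 2-fold higher in the DAC library and 44 at least 2-fold lower. The higher genes held 35 protein-coding genes and 100 small RNAs, with 56 genes listed at 0 untreated, and all 44 lower genes were small RNAs. The median of all kept genes was 0.07. A counting interval wholly beyond 2-fold was met by 36 of the 138 and 0 of the 44. The small RNAs MIR6847, MIR6820, SNORD54, MIR6734 and MIR762 were named on the higher side and MIR6733, MIR548AR, MIR3188 and MIR7107 on the lower, each on few reads. RN7SK (2.48 and 20.4 FPKM) and BCYRN1 (3.08 and 14.0 FPKM), noncoding RNAs with many copies in the genome, were higher.

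Interferon-stimulated genes of THP-1 had 3 of 37 past 2-fold higher and 0 lower, with a median of 0.54 (random 0.02 to 0.17). Beside LGALS3BP and IFI27, IFITM3, which restricts virus entry, stood at 35.9 FPKM untreated and 76.2 with DAC, which falls just below 2-fold (log2 0.99) under median-of-ratios scaling. Cancer-testis genes had 1 of 5 higher and 0 lower (median 0.42, random -0.13 to 0.30), with PRAME at 64.3 and 86.5 FPKM. Of 50 members with values, 21 were above 0 in at least 1 library. Their median was 0.14, above its random lists, while the rest were at 0 in both libraries. Germline genes had 2 of 6 higher and 0 lower (median 0.30, inside its random range of -0.12 to 0.44). These were TUBA3D (0.25 and 2.40 FPKM) and TUBA3C (0 and 1.38 FPKM). Over the 31 germline genes above 0 in at least 1 library the median was 0.08 and stood above its random lists. Monocyte and macrophage genes had 2 of 27 higher and 0 lower (median 0.32, random -0.03 to 0.12), LGALS2 (1.56 and 5.59 FPKM) and MMP9, a secreted protease (7.97 and 19.8 FPKM). Myeloid progenitor genes had 0 of 19 past 2-fold at a median of -0.12 (random -0.07 to 0.11), with PRTN3, a granule protease of immature myeloid cells, at 487 and 324 FPKM. Lymphoid genes had 1 of 5 higher (median 0.37, random -0.12 to 0.35), PRF1 (0.04 and 1.55 FPKM). That list was no longer apart with genes of at least 5 FPKM or a pseudocount of 0.1, and its median was 0.16 without the filter.

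Direct p53 targets of THP-1 had 0 of 52 past 2-fold, and their median of 0.21 lay above the random range of 0.02 to 0.14. CDKN1A stood at 33.0 FPKM untreated and 47.7 with DAC (log2 0.52), and MDM2 at 8.74 and 10.0. MHC class I genes had 0 of 14 past 2-fold (median 0.19, random -0.11 to 0.08), with NLRC5, their transactivator, at 12.6 and 19.2 FPKM. Sensors of double-stranded RNA had 0 of 10 (median 0.22, random -0.05 to 0.21), NF-kB genes 0 of 18 (median 0.18, random -0.04 to 0.16), and Fanconi anaemia and homologous recombination genes 0 of 28 (median 0.20, random -0.01 to 0.14). The list of double-stranded RNA sensors was no longer apart under both filters and both other pseudocounts. On the lower side, glycolysis and hypoxia genes had 0 of 17 past 2-fold at a median of -0.34 (random -0.08 to 0.11). Among them ALDOC, a glycolytic aldolase, stood at 63.0 and 35.8 FPKM and BNIP3, a mitophagy receptor, at 50.2 and 28.8. Sterol synthesis genes (median -0.24, 0 of 19 past 2-fold, random -0.07 to 0.10) and stress response genes (median -0.21, 0 of 19, random -0.08 to 0.10) lay lower too. DNMT1 (106.0 and 109.6 FPKM), DNMT3A (11.1 and 11.8 FPKM) and DNMT3B (5.95 and 5.88 FPKM) differed little. DNA replication (median 0.06, 36 kept) and ribosomal protein genes (median -0.02, 40 kept) had 0 members past 2-fold and lay inside their random ranges, and the former median turned negative under median-of-ratios scaling. No value under these symbols was listed in THP-1 for the mitochondrially encoded mRNAs or the replication histones.

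Genes that were higher in both DAC libraries were led by MAGEA4 and PNMA5. In HCC1937 both were listed at 0 untreated, with 33.0 and 27.6 FPKM after DAC. IFI27 was 5.41-fold higher in HCC1937 (counting interval 5.16 to 5.67) and 9.39-fold higher in THP-1 (5.07 to 20.9). PTGDS, a prostaglandin synthase, stood at 0.02 and 3.19 FPKM in HCC1937 and 0.70 and 3.82 in THP-1. SPARC, a matrix glycoprotein, stood at 6.54 and 16.3 FPKM in HCC1937 and 0.24 and 2.57 in THP-1. TUBA3D, UNC13D and MIR6772, the last on few reads, were higher in both as well. Under upper-quartile scaling SPARC and UNC13D drop below 2-fold in HCC1937. Of 9798 genes kept in both lines, 448 were higher in HCC1937 and 33 in THP-1, and 15 were shared, where independent lists would share 1.51. In opposite directions, 5 genes were lower in HCC1937 and higher in THP-1, against 0.266 for independent lists, and 1 was higher in HCC1937 and lower in THP-1, against 0.229. Independent lists treat every kept gene as equally likely to be called. Since opposite directions exceeded them too, an excess alone does not show a shared response. On the lower side 79 and 5 genes shared 4, against 0.0403 for independent lists. These 4 were the small RNAs MIR339, MIR4322, MIR4653 and SNORA59A, and 0 were shared once short genes were left out. Across genes, which are not independent replicates, the log2 differences of both lines had a Pearson r of 0.22 and a Spearman rho of 0.22. The genes higher in HCC1937 had a median of 0.13 in THP-1, against 0.06 for all shared genes.

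**Figure D3:**
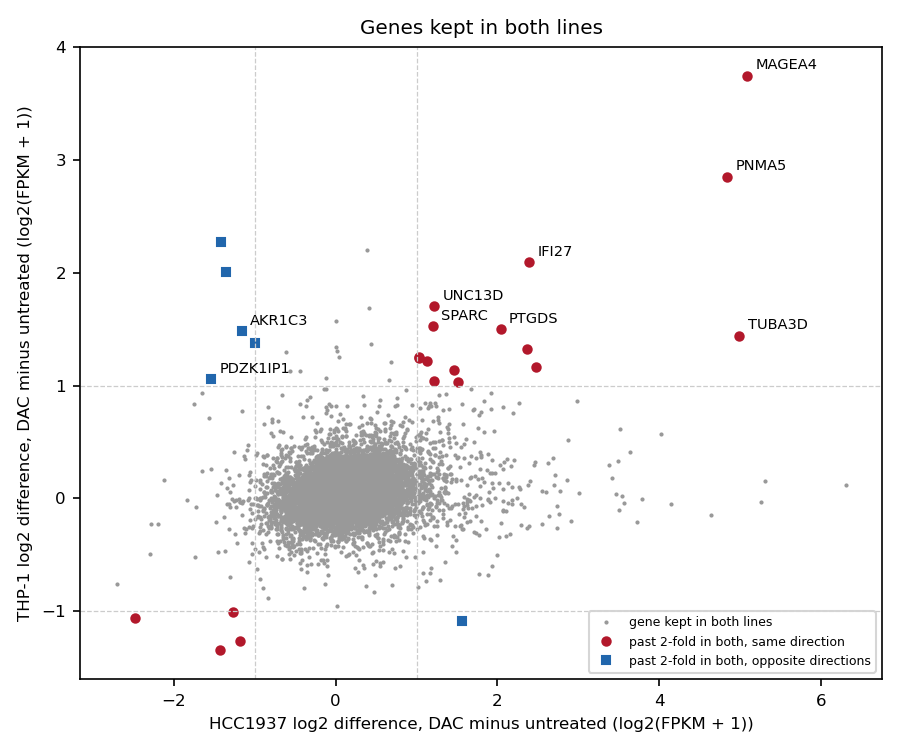
Log2 difference (DAC minus untreated, on log2(FPKM + 1)) in HCC1937 (horizontal) and THP-1 (vertical) for genes kept in both lines. Red circles are past 2-fold in both lines in the same direction, 15 higher and 4 lower, blue squares in opposite directions, and dashed lines mark 2-fold.

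Over both lines as the only replication of the treatment, limma (design with line and treatment, 1 residual degree of freedom) called 0 genes higher and 0 lower of 12815 tested. At an unadjusted p under 0.05 there were 506 higher and 110 lower genes, 616 in all, where chance alone gives 641. The split was 331 and 230 under median-of-ratios scaling and 447 and 302 under upper-quartile scaling. IFI27 (log2 2.24, SE 0.17) and MAGEA4 (log2 4.42, SE 0.35), higher in 2 of 2 lines, had the smallest adjusted p, 0.584. Adjusted over the list alone, 10 of 41 interferon-stimulated genes passed, all higher in 2 of 2 lines, and 0 passed over all genes tested. IFI27 had an adjusted p of 0.00254 over that list and OAS3 0.0408 (log2 1.32, SE 0.22). IFI6, ISG15, IFITM1, OAS1, OAS2, RSAD2 and PARP9 were among the rest. Of these, the last 6 names were chosen after their values were seen.

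Of 6 cancer-testis genes, 3 passed adjusted over the list alone and 0 over all genes, namely MAGEA4 (limma adjusted p 0.000547 over the list), PRAME and VCX (both 0.0408), each higher in 2 of 2 lines. Single members passed adjusted over the list alone for TUBA3C among germline genes, MMP9 among monocyte genes and, on the lower side, ALDOC among glycolysis genes (log2 -0.85, SE 0.14, limma adjusted p 0.0465). COL1A1 and SPARC passed among mesenchymal genes (both 0.0123 by limma). These came to 18 calls in 6 of 29 lists, with no adjustment across the lists and 0 calls over all genes. The interferon count is 2 under median-of-ratios scaling, 4 with a pseudocount of 0.1, 1 without a filter and 0 without the line as a block. The cancer-testis count is 1 with that pseudocount, 0 without a filter and 1 without the block. The germline, monocyte, glycolysis and mesenchymal counts are all 0 without a filter and 0 without the block. With that pseudocount the glycolysis count is 0 and the mesenchymal count 1, and without the trend the glycolysis count is 0. Under upper-quartile scaling the germline and monocyte counts are 2. Dose and days differ between the lines, so the fit averages unlike treatments.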

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

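Tests of scaling, overall and past 4-fold, and of protein-coding genes, THP-1 RNA, the gene set, depth and the shared dose were chosen after the results were seen, and those of background reads and counting error before. Differences between the lines in this part were not tested, since each line has 1 library per group and dose and days differ.

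Gene lists that stood apart in opposite directions in the lines were NF-kB and inflammatory genes and myeloid progenitor genes. The NF-kB median was -0.16 in HCC1937 and 0.18 in THP-1, a difference of -0.34. The myeloid progenitor median was 1.56 over 3 genes in HCC1937 and -0.12 over 19 in THP-1, a difference of 1.67. In HCC1937 neither list stood apart without a filter on low values. Single genes past 2-fold in opposite directions were AKR1C3, a steroid-converting reductase, and PDZK1IP1. AKR1C3 stood at 8.93 and 3.44 FPKM in HCC1937 and at 3.07 and 10.4 in THP-1, a log2 difference between the lines of -2.65, and it has close paralogs. PDZK1IP1 stood at 75.7 and 25.5 FPKM in HCC1937 and at 0 and 1.08 in THP-1, a difference of -2.59. The small RNAs RNU6-45P (-2.38), SNORA49 (2.66), SNORD11 (-3.36) and SNORD14E (-3.69) did so on few reads. Among table lines with a repeated symbol, which no comparison used, 7 in HCC1937 and 7 in THP-1 were at least 2-fold higher with DAC.

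Far more genes were higher than lower in the HCC1937 DAC library, with a ratio of 7.19. Small RNAs with few reads are not the cause, since the ratio was 10.4 among protein-coding genes. A background of reads over all genes, such as genomic DNA, is not the cause among protein-coding genes either. The 4630 of them listed at 0 untreated had a median of 0 FPKM with DAC. Of these, 2953 stayed at 0, and their 90th percentile was 0.21 FPKM. This was not examined for the 483 higher genes of other or no type. Genes above 0 numbered 22532 in the untreated library and 26633 in the DAC library. Scaling is not the cause for the genes past 4-fold, whose ratio was 22.6 as deposited and stayed at 11.8 or more under both scalings. The 380 higher genes listed at 0 untreated say nothing on the excess by themselves, since any such gene that passes the filter is called higher. For smaller differences scaling stays open as a part of the excess, since the ratio past 2-fold was 2.18 under upper-quartile and 4.18 under median-of-ratios scaling, and an effect of DAC on silenced genes stays a hypothesis without replicates.

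Of the myeloid progenitor, monocyte and lymphoid markers, 9 were higher in the HCC1937 DAC library. RNA of THP-1 cells could carry 8 of them, LCK being listed at 0 in THP-1. These 8 would need THP-1 shares of 1.75% to 55.7%, while 20 protein-coding genes abundant in THP-1 and under 0.05 FPKM in untreated HCC1937 had a median share of 0.508% and 14 of 20 lay below the lowest need. The set and the bound of this test, 0.5 times that need (0.877%), were changed after the values were seen from 0.1 times (0.175%), which would leave the median undecided. Genes listed at 0 may not have been counted and gene lengths differ between the lines, and the median was 0.648% without the 3 genes at 0, 0.739% on estimated reads and 0.890% with both, just above the bound, yet AZU1 at 0.0386% and ELANE at 0.0148% were counted and lie far below any need. Counting error is not the cause, since 100% of the 9 have a counting interval beyond 2-fold, and an effect of DAC in HCC1937 cells stays open as a hypothesis.

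Fewer genes were past 2-fold in THP-1 than in HCC1937. The smaller gene set of THP-1 is not the cause, since over the genes kept in both lines 527 and 38 were past 2-fold, a ratio of 13.9. Lower depth is not the cause, since the shallower THP-1 library had 1.04 times the counted reads of the shallower HCC1937 library. Dose, days and line may each contribute and cannot be told apart, since the lines share 0 combinations of dose and duration.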

How the results depend on the processing

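Alternatives on the counting interval, short genes, and limma with upper-quartile scaling or without the trend were chosen after seeing the data. Counts are given against the reported 1452 higher and 202 lower genes in HCC1937, 138 and 44 in THP-1, and 15 and 4 in both lines. Of the lists apart in HCC1937, all but p53 targets and monocyte genes stayed apart under both scalings. Scaling moves the random lists by nearly the same amount as the list, so this standing could hardly change and is no test of scaling. The epithelial median went from 0.11 to -0.17 under upper-quartile scaling, while its percentile went from 97.7 to 98.8.

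With genes of at least 5 FPKM the counts were 550 and 108 in HCC1937, 42 and 4 in THP-1, and 5 and 0 in both, as fewer genes were examined. At 1.5-fold they were 3084 and 831, 398 and 121, and 79 and 10, and at 4-fold 294 and 13, 13 and 3, and 3 and 0, as the rule itself implies. With a pseudocount of 0.1 they were 2323 and 383 in HCC1937, 297 and 74 in THP-1, and 47 higher in both. Without a pseudocount they were 2454 and 416, 315 and 102, and 55, since a smaller pseudocount widens differences at low values. Under upper-quartile scaling 487 genes were lower in HCC1937 and 8 higher in both lines, as this scaling takes 0.31 off the log2 differences of HCC1937. With the counting interval wholly beyond 2-fold, 120 genes were lower in HCC1937, 49 higher and 2 lower in THP-1, and 0 lower in both. Without short genes, and with them genes without a length, 131 were lower in HCC1937, 38 higher and 0 lower in THP-1, and 0 lower in both. The other counts stayed within 1.5 times.

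The limma count of 0 became 3 higher under upper-quartile scaling (MAGEA4, IFI27 and PNMA5, named after their values were seen), and the cause was not tested. It stayed at 0 higher and 0 lower under median-of-ratios scaling, without a filter, with a pseudocount of 0.1, without the trend, without short genes, at an adjusted p of 0.1 and without the block, where 3 genes higher and 0 lower had an unadjusted p under 0.05. The correlation of 0.22 was 0.157 without a filter, 0.257 at 5 FPKM and 0.238 without short genes, and the cause was not tested. The HCC1937 monocyte list went from the 97.8th percentile of its random lists over 11 genes to 3.98 over 4 genes at 5 FPKM. That filter took out the higher genes TYROBP, GPNMB and CSF1R, at 3.24, 1.84 and 1.54 FPKM with DAC, so the lists compared hold different genes. Scaling to library totals equals the deposited values. Tests on counts were not run, since the values were taken as FPKM. Reads estimated from them served only for the counting intervals, the simulation and the test of THP-1 RNA. Leaving out a line leaves no residual degree of freedom. Depth limits the small RNAs most, where a few reads make a 2-fold difference.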

Other observations

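The tests of the X chromosome and of genes that THP-1 expresses were fixed before their results were seen, and the genes named beside them were chosen after their values were seen.

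Several groups of genes not described above lay inside their random ranges in HCC1937. Imprinted genes had 2 of 12 higher in the DAC library (median 0.33), NNAT and H19, the latter a noncoding RNA listed at 0 untreated and at 3.43 FPKM with DAC. Endothelial markers had 2 of 5 higher (median 0.58), such as PECAM1, an adhesion molecule (1.71 and 5.13 FPKM). Megakaryocyte and platelet markers had 1 of 5 higher (median 0.71), VWF (0.13 and 1.29 FPKM). Under upper-quartile scaling PECAM1 dropped below 2-fold, and VWF did under both scalings. Genes that take up and process decitabine had 1 of 17 higher, SLC29A1, a nucleoside transporter (8.52 and 18.96 FPKM), and 0 of 17 under both scalings. Their median of 0.23 turned negative under upper-quartile scaling. DNA methylation genes had 1 of 14 higher (median 0.31), DNMT3B. Glycolysis and hypoxia genes had 1 of 18 higher (median -0.04), CA9, listed at 0 untreated and at 1.46 FPKM with DAC. MHC class I genes had 1 of 16 lower, PSMB10, an immunoproteasome subunit (62.6 and 29.5 FPKM), and BCL2 family genes 1 of 14 lower, BBC3, a p53-induced promoter of apoptosis (22.9 and 10.3 FPKM). Sensors of double-stranded RNA (median 0.33), MHC class II genes (-0.04) and housekeeping genes (-0.17) had 0 members past 2-fold. Without a filter on low values the imprinted (98.7th percentile) and megakaryocyte (99.1th) lists stood above their random lists and the MHC class II list (2.27th) below.

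In THP-1, megakaryocyte and platelet markers stood above their random range with 0 of 4 past 2-fold (median 0.34, random -0.12 to 0.32), and were no longer apart without a filter on low values or with a pseudocount of 10. Mesenchymal genes had 3 of 13 higher (median 0.05), SPARC, COL1A1 and PDGFRB, a growth factor receptor (0.38 and 1.78 FPKM), the last below 2-fold under both scalings. Epithelial genes had 1 of 8 higher (median 0.19), KRT17 (0.52 and 2.75 FPKM). Imprinted genes (median 0.15), decitabine metabolism (0.08), metallothioneins (0.10), BCL2 family (0.06), DNA methylation genes (0.01), G2/M genes (0.01), protocadherin beta genes (-0.06), MHC class II genes (0.03), endothelial markers (0.03) and housekeeping genes (-0.01) had 0 members past 2-fold and lay inside their random ranges. The mesenchymal, DNA methylation, G2/M, MHC class II and endothelial medians turned negative under both scalings, and that of the BCL2 family under median-of-ratios scaling. Globin and erythroid genes had 0 kept members in either line.

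A hypothesis is that genes silent in HCC1937 respond to DAC more often on the X chromosome, even outside the cancer-testis list. Of protein-coding genes under 0.1 FPKM untreated and outside that list, 23 of 360 on X (6.39%, 95% Wilson interval 4.30 to 9.40) and 210 of 5849 on autosomes (3.59%, 3.14 to 4.10) reached 1 FPKM with DAC. The ratio of 1.78 is consistent with it. The list does not hold every testis gene of X, gene families are not independent, and X and autosomal genes may differ in other ways.

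Another hypothesis is that silent protein-coding genes which another cell type expresses are raised more readily than genes silent in both lines. Of protein-coding genes under 0.1 FPKM in untreated HCC1937, 42 of 305 with at least 5 FPKM in untreated THP-1 (13.8%, 10.4 to 18.1) reached 1 FPKM with DAC. Of those under 0.1 FPKM in THP-1 as well, 148 of 4025 did (3.68%, 3.14 to 4.30). The ratio of 3.75 is in line with it, and examples are GSTP1, TKTL1, CST3 and HCLS1. CST3, a secreted protease inhibitor, was listed at 0 and stood at 12.9 FPKM with DAC, against 89.4 in untreated THP-1, whose values rest on other gene lengths. Differences in promoter type were not examined, so a shared cause could give the same ratio.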
